A study of Mus musculus and Homo sapiens with 10 samples.

How the data were processed

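Per the labels' protocols, Dam fusion proteins were induced with 2 µg/mL doxycycline, and for Nanopore-DamID 2.5 µg of genomic DNA was dephosphorylated, cut at methylated GATC sites with DpnI, A-tailed and prepared with a ligation kit, with no amplification step described. Per the same labels, Illumina-DamID libraries followed a published protocol. The submitters' processing notes name minimap2, SAMtools, deepTools and bedtools and the builds mm10 and hg38, without roles or versions. The caller, its thresholds and the samples that entered each list are not given in the sources used here. In particular, it is open whether the sample labelled 10% LaminB1-Dam entered the Nanopore list, and so whether it is a consensus of 1 or of more samples.

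The values used were 3 lists of interval coordinates that the authors deposited, with no score, height or p-value per interval: consensus LADs by Nanopore (1210 intervals), consensus LADs by Illumina (1190) and CTCF peaks by Nanopore (10912). LAD borders lay on a 20 kb grid in 100% of cases on chromosomes 1 to 19 and X. Scaffold names in the LAD lists belong to mm10; the CTCF list was taken as hg38 from the cell line and the builds named. With no counts in the lists, depth per sample and its precision are unknown. Dam-only and wild-type samples, whose role in the calls is not given in the sources used here, were not analysed. Intervals on shares cover counting error only.

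LADs were analysed on chromosomes 1 to 19 and X in bins of 20 kb, over the span from the first to the last gene or LAD. Genes came from an annotation of GRCm38.p6, the assembly behind mm10, with 49997 rows; 340 genes listed below 3 Mb, where the placed sequence of these chromosomes starts, were taken as genes of unplaced scaffolds and left out. The annotation used has no strand, so each gene was placed by its midpoint in place of the transcription start site that had been planned. Overlap was tested with 100000 rotations of the Nanopore LADs within chromosomes, counts of LADs and border distances with 1000, and gene lists with 10000, 2-sided with Benjamini-Hochberg adjustment over 25 mouse lists. Rotation keeps LAD sizes and spacing. Coverage and gene density were compared over 20 chromosomes with 100000 sign flips, and widths with 100000 resamples. Of the planned measures for regions of a single method only gene density was computed, so no adjustment over measures was made. CTCF peaks were compared with 100000 multinomial draws by the span from first to last peak, in place of chromosome length. Gaps were compared with 1000 random placements without overlap in that span, and windows with 1000 random sets of points in it, which may overlap. Adjusted p-values were called at 0.05.

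The gene lists, main tests, main alternatives and the rule for named genes were chosen before the data were examined. Named genes are protein-coding genes wholly inside the 10 widest regions shared by both lists, in Nanopore LADs only and in Illumina LADs only, at most the 3 longest of each, leaving out genes without an annotated name. Members of lists given gene by gene may be named as examples, and of lists given by a symbol pattern at most 4 of each class in alphabetical order. Olfactory and other families were found by such patterns, which also take in the interferon receptors and Grid2ip. Sfmbt2, Mirg, Pcdhb22, the counts of kallikrein genes and the gene families of the closing section were chosen after their values were seen. Values of some single genes are not reported here. The rule for genes at CTCF peaks was not applied, as no human annotation was used. The test of CTCF clustering and rotation along the gene order, in which LAD status moves over the order of protein-coding genes, were chosen after the data were seen. Methods were tested on simulated data. In the rotation test along the sequence, 2% of 200 lists of 20 random positions fell under 0.05 and 93% of lists with 80% of members planted in LADs were recovered. Planted members were scattered over LADs, so this recovery does not apply to lists of neighbouring genes. Of 200 lists of 20 random protein-coding genes 59% fell under 0.05, all of them below rotation, so a call below in this test reflects in part that genes are sparse in LADs. Along the gene order, 2% of lists of random runs of neighbouring genes fell under 0.05 and 100% of planted lists, again with scattered members, were recovered. Rotated copies of the LADs gave 2% in the overlap test, sign flips on noise gave 4%, a shift of 40 kb came back as 40 kb, and random CTCF placements gave 5%, while all 100 placements with 30% of peaks planted as neighbours were recovered.

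Alternatives left out chromosome X or LADs under 100 kb, merged near LADs, added chromosome Y, changed the shared fraction, placed genes by whole length or any overlap, and used Fisher's exact test. Tests that need sequence or a human annotation were not run. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.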

Results

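DamID maps where a chromatin protein sits by fusing it to the bacterial adenine methyltransferase Dam, which marks GATC sites near the protein's binding places. The study set a version read on Nanopore instruments beside the established version read on Illumina instruments. The 10 samples fell into 8 groups. In N2A cells, a mouse neuroblastoma line, 7 samples covered LaminB1-Dam and Dam alone by both methods, a sample labelled 10% LaminB1-Dam and a wild-type sample; LaminB1-Dam by Illumina had 2 samples and each other N2A group had 1. In HEK293T cells, a human kidney-derived line, 2 samples carried CTCF fused to the mutant DamN126A and 1 carried DamN126A alone. The values analysed were 3 lists of intervals: lamina-associated domains (LADs, stretches of chromatin at the nuclear lamina) from each method in N2A cells, and CTCF peaks in HEK293T cells. The lists gave positions without per-sample values, so sequencing depth was unknown and no spread between replicates could be computed.

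The first comparison asked whether both methods marked the same chromatin as LADs. The widest region shared by both lists spanned 19.56 Mb of chromosome 16 (64900001 to 84460000, mm10) and held Robo1 and Robo2, which encode axon guidance receptors, and Cadm2, a cell adhesion gene. The next widest, 12.1 Mb of chromosome X (111360001 to 123460000), held Pcdh11x, Dach2 and Tex16. A stretch of 11.52 Mb on chromosome 14 (87480001 to 99000000) held the protocadherin gene Pcdh9 with Klhl1 and Dach1, and another of 10.9 Mb there (105980001 to 116880000) held Gpc5, Trim52 and Slitrk5. Other regions among the 10 widest held the cadherin genes Cdh12, Cdh10 and Cdh6 on chromosome 15 (12960001 to 23440000), Pcdh7, Arap2 and Dthd1 on chromosome 5, Pcdh10, Pcdh18 and Pabpc4l on chromosome 3, Edil3, Mef2c and Vcan on chromosome 13, Adgrl3, Epha5 and Tecrl on chromosome 5, and Cntnap5b, Cdh20 and Slco6d1 on chromosome 1.

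On chromosomes 1 to 19 and X, 1174 Nanopore LADs covered 1480.1 Mb and 1149 Illumina LADs covered 1353.06 Mb of a span of 2570.96 Mb. The lists shared 1336.08 Mb. A further 144.02 Mb lay in Nanopore LADs only, 16.98 Mb in Illumina LADs only and 1073.88 Mb in neither. The Jaccard index, shared bases over bases in either list, was 0.892. Rotating the Nanopore LADs along each chromosome gave a mean of 0.384 and a highest value of 0.456 (1-sided permutation test by rotation, p = 1e-05, the smallest that 100000 rotations can give). Nanopore LADs held 98.7% of Illumina LAD bases, and Illumina LADs held 90.3% of Nanopore LAD bases.

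Of the Illumina LADs, 1117 of 1149 (97.2%, 95% Wilson interval 96.1 to 98.02%) had at least 50% of their bases in Nanopore LADs. In the other direction, 924 of 1174 Nanopore LADs (78.7%, 76.3 to 80.95%) had at least 50% of their bases in Illumina LADs. Both counts were above all 1000 rotations (1-sided permutation by rotation, p = 0.001, the smallest that they can give). Rotation gave 682.7 and 631.8 LADs on average. With 50% shared both ways between single LADs, 877 LADs of each list passed, 76.3% of Illumina and 74.7% of Nanopore LADs. Rotation then gave 147 on average in each direction. By the plain 50% rule, Nanopore LADs under 200 kb passed in 39.2% of 194 cases, against 98.1% of 211 LADs of 2 Mb or more. Illumina LADs under 200 kb passed in 87.8% of 205 cases. Illumina LADs covered 52.6% of the span and Nanopore LADs 57.6%. The share for narrow Nanopore LADs was thus not above what coverage alone would give. Width classes were not tested by rotation. The median distance from an Illumina border to the nearest Nanopore border was 20 kb, the width of a grid step, against 445 kb after rotation (1-sided permutation by rotation, p = 0.001). Median widths were 690 kb for Nanopore LADs and 660 kb for Illumina LADs, a difference that did not pass the test (2-sided permutation, p = 0.559). LADs of a single genome are not biological replicates.

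Chromosome X had the largest gap in coverage between the methods, with 68.1% of its span in Nanopore LADs and 57.3% in Illumina LADs. Chromosome 2 followed at 53.7% and 45.7%, and chromosome 12 had the smallest gap, 56.2% and 54.7%. Chromosome 19 had the lowest coverage with either method, 42.5% and 36.3%. Nanopore coverage was higher on 20 of 20 chromosomes, at 56.8% ± 6.13 (SD over 20 chromosomes) against 51.9% ± 6.04. The difference was 4.87 ± 2.31 percentage points (2-sided sign-flip permutation test over chromosomes, p = 1e-05, the smallest that 100000 flips can give). Chromosomes stand in for units here and are not biological replicates.

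**Figure D1:**
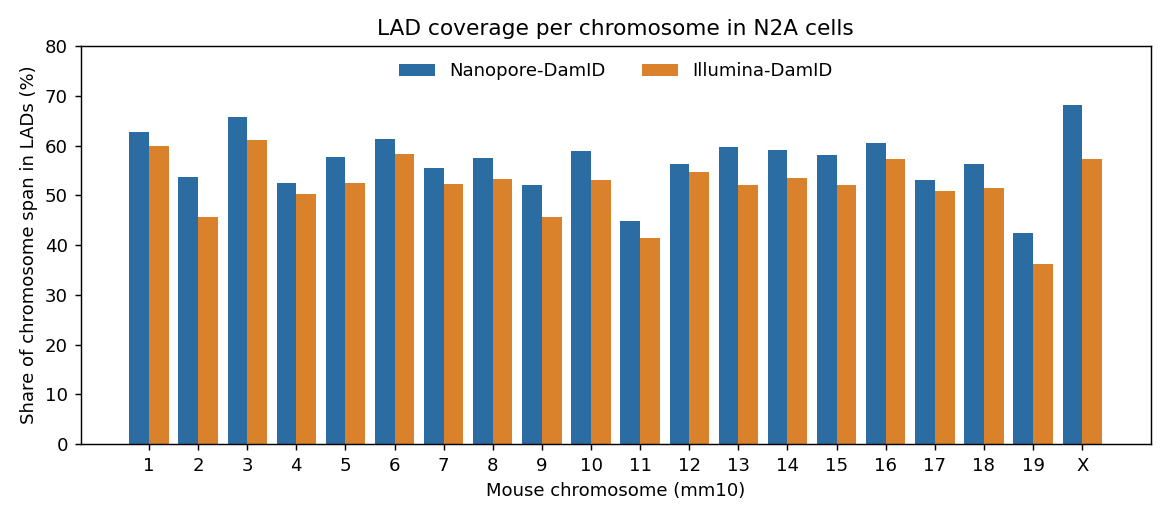
Share of each mouse chromosome's span in LADs (percent, vertical axis) for Nanopore-DamID (blue bars) and Illumina-DamID (orange bars), by chromosome (horizontal axis). Each bar is 1 consensus list, without error bars; the blue bar is higher on all 20 chromosomes, with the widest gap on X (68.1% against 57.3%).

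Protein-coding genes were sparse in LADs of both lists. Of 21523 genes, 6223 (28.9%) had their midpoint in a Nanopore LAD and 5469 (25.4%) in an Illumina LAD. By both lists together, 5324 genes lay in LADs of both methods, 899 in Nanopore LADs only, 145 in Illumina LADs only and 15155 in neither. Gene density was 4.32 ± 1.63 per Mb inside and 13.9 ± 3.14 per Mb outside Nanopore LADs (SD over 20 chromosomes), and 4.19 ± 1.79 against 13.1 ± 3.04 per Mb for Illumina LADs. Density was lower inside on 20 of 20 chromosomes with each list (2-sided sign-flip permutation test, p = 1e-05 for each).

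Olfactory receptor genes, a large family of odorant receptors used in the nose, lay in LADs for the most part. Of 1109 members, 1038 (93.6%) were in Nanopore LADs and 1005 (90.6%) in Illumina LADs, 1001 of them in both; Olfr1 and Olfr10 were examples inside both. Vomeronasal receptor genes, which serve pheromone sensing, had 302 and 294 of 350 members in Nanopore and Illumina LADs. Of 30 long genes for neural adhesion and synapses, 26 were in LADs with each method and 25 with both, among them Cntn5 (chromosome 9, 9634223 to 10904775), Csmd1 (chromosome 8, 15892538 to 17535385) and the dystrophin gene Dmd (chromosome X, 82814664 to 85205050). The exceptions were Lrp1b (chromosome 2, 40595290 to 42653598), with its midpoint in an Illumina LAD only, Ntm (chromosome 9, 28994749 to 29963269), in a Nanopore LAD only, and Dlg2, Dscam and Opcml, in neither. Rotated Nanopore LADs held 53.9% of olfactory receptor, 57.1% of vomeronasal receptor and 58.0% of the neural genes on average. All 3 lists were above rotation with both methods (2-sided permutation by rotation, Benjamini-Hochberg over 25 lists; adjusted p = 0.0005 for each receptor family and 0.00273 for the neural genes by Nanopore, 0.000556 and 0.00136 by Illumina). When any overlap counted in place of the midpoint, the neural list lost its call with Nanopore LADs (permutation, adjusted p = 0.133) and kept it with Illumina LADs (0.0368).

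Housekeeping, cell cycle, proteasome, ribosomal protein and mitochondrial complex I genes lay mostly outside LADs. None of 18 housekeeping genes such as Actb and Gapdh, none of 18 cell cycle genes such as Mki67 and Top2a and none of 39 proteasome subunit genes lay in a LAD of either list. Ribosomal protein genes had 4 and 2 of 84 members in Nanopore and Illumina LADs, with Rpl10l and Rpl39l in both and Rpl31 and Rps12 by Nanopore only. Mitochondrial complex I genes had 3 and 4 of 49, with Ndufaf4, Ndufaf5 and Ndufb4b in both and Ndufaf7 by Illumina only; the Ndufaf genes encode assembly factors. Each of these 5 lists was below rotated LADs with both methods (2-sided permutation by rotation, adjusted p = 0.0005 by Nanopore and 0.000556 by Illumina). That test sets genes against sequence as a whole, and in simulation it also called 59% of lists of 20 random protein-coding genes below Nanopore LADs rotated in this way, so by itself it does not set a list apart from other genes. Each of the 5 lists was also below other genes in a permutation that rotated LAD status along the order of protein-coding genes, a test chosen after the data were seen, with adjusted p from 0.001 to 0.00727 by Nanopore and from 0.001 to 0.024 by Illumina.

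Of 24 genes that mark the neuroblast lineage, 21 lay in neither list, among them Mycn and Hand2. Isl1 (chromosome 13, 116298270 to 116309688) was among those in both, and Th, the tyrosine hydroxylase gene of catecholamine synthesis (chromosome 7, 142892779 to 142899995), lay in a Nanopore LAD only. Of 15 genes for lamina proteins and DNA methylation, 14 lay in neither list, among them Lmnb1, Lbr and Dnmt1, and Tet2 (chromosome 3, 133463677 to 133545136) lay in both. Zfp zinc finger genes had 132 and 116 of 397 members in Nanopore and Illumina LADs. These 3 lists were below rotated LADs (permutation by rotation, adjusted p = 0.0005 by Nanopore; 0.000556 by Illumina, and 0.001 for the lamina list). Against other genes in the gene order none kept its call, with adjusted p by permutation of 0.151, 0.121 and 0.523 by Nanopore and 0.116, 0.206 and 0.658 by Illumina for the neuroblast, lamina and Zfp lists. The Zfp genes then turned direction, at 33.2% against 29.7% by Nanopore and 29.2% against 26.5% by Illumina.

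Bitter taste receptor genes had 33 and 31 of 35 members in Nanopore and Illumina LADs, and Cyp2 and Cyp3 genes, which encode cytochrome P450 enzymes, had 44 and 43 of 56. Keratin and keratin-associated genes had 82 and 59 of 109, with 23 by Nanopore only, such as Krt1 and Krt10, and none by Illumina only. None of these 3 lists was called by rotation along the sequence (permutation, smallest adjusted p = 0.153), where rotated Nanopore LADs held 2 to 35 of the 35 bitter taste receptor genes (95% range). Against other genes in the gene order each was above (permutation, adjusted p = 0.0025, 0.00389 and 0.0025 by Nanopore and 0.0282, 0.00333 and 0.0283 by Illumina for bitter taste receptor, Cyp and keratin genes). Of 27 glutamate receptor genes, counted with Grid2ip, 15 and 14 were in LADs, Gria1, Gria2, Gria4 and Grid1 in both. Their share was not called against rotated LADs, which held 56.4% and 51.8%, and was above other genes in the gene order, 30.0% and 26.7% (permutation, adjusted p = 0.0117 and 0.0225). Defensins had 55 and 52 of 71 members in LADs and passed against the gene order by Illumina only, a difference between methods that was not tested (permutation, adjusted p = 0.055 and 0.0385).

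Further lists had no call by either rotation with either method. The Skint family had 8 of 11 members in LADs of each list, type I interferons with their receptors 1 of 20 (Ifnk), blood and immune genes 4 of 15, with Ptprc and Ms4a1 inside, and liver genes 7 of 15, with Alb and Afp inside. Muscle genes had 8 and 7 of 17, with Ttn in both and Neb by Nanopore only. Liver and muscle genes were below rotated LADs and above other genes in the gene order with both methods, without a call either way. Imprinted genes had 7 and 8 of 24, with Igf2 by Nanopore only and Grb10 and Magel2 by Illumina only. UDP-glucuronosyltransferase genes had 13 of 22 in each list. In Fisher's exact test, which treats neighbours as independent, they were 30.2 points above other genes by Nanopore, a turn from just below rotated LADs, and 33.7 points above by Illumina (adjusted p = 0.00593 and 0.00187). That test also called the Skint family above other genes with both methods, by 43.8 and 47.3 points (Fisher's exact test, adjusted p = 0.00592 and 0.00277). Type I interferons were called below by Nanopore, at -23.9 points, and not by Illumina, at -20.4 (Fisher's exact test, adjusted p = 0.0199 and 0.0554), a difference between methods that was not tested. Blood and immune, liver, muscle and imprinted genes had no call in it, and defensins were above with both methods (Fisher's exact test, adjusted p = 1.9e-16 and 3.1e-16).

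**Figure D2:**
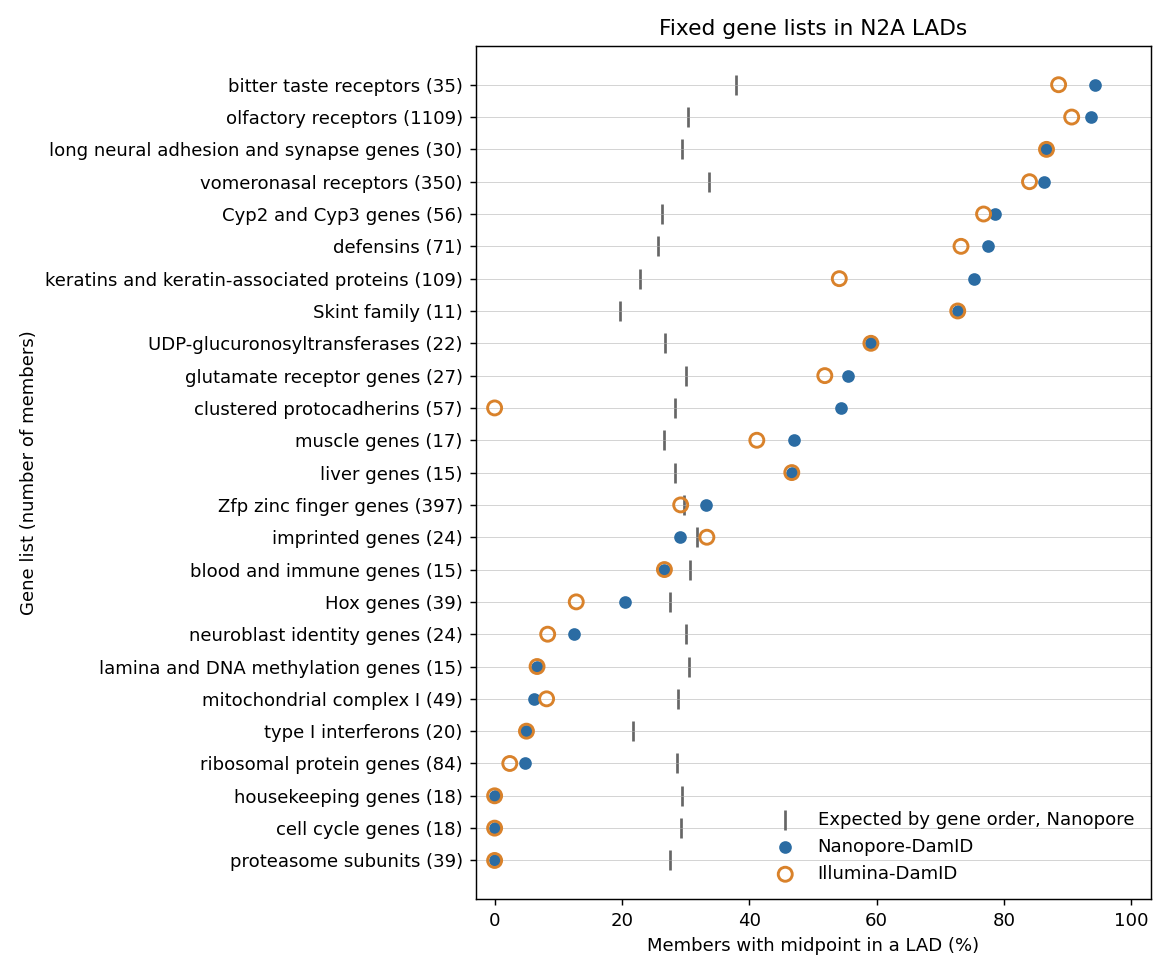
Share of each fixed gene list with its midpoint in a LAD (percent, horizontal axis) for Nanopore-DamID (filled blue) and Illumina-DamID (open orange), with the number of members beside each list (vertical axis). Grey ticks give the share expected for Nanopore LADs when LAD status is rotated along the gene order; olfactory (93.6% and 90.6%) and vomeronasal receptors lie right of their ticks and proteasome, cell cycle and housekeeping genes lie at 0.

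Both lists differed at the clustered protocadherins, neuronal cell surface proteins encoded side by side on chromosome 18. By Nanopore, 31 of 57 members had their midpoint in a LAD, including all 22 Pcdhb genes, and by Illumina none did. Nanopore LADs ran from 36800001 to 37080000, at the Pcdha genes, and from 37220001 to 37760000. Illumina LADs ran from 36840001 to 36920000, before the first Pcdha gene, and from 37520001 to 37620000. The latter overlapped 1 Pcdhb gene, Pcdhb22. Pcdha genes share their last exons and Pcdhg genes likewise, so their midpoints depend on that shared end: 12 of 14 Pcdha and 17 of 21 Pcdhg genes overlapped a Nanopore LAD, against 6 and 3 by midpoint. The list was not called (permutation by rotation, adjusted p = 0.988 and 0.668), and rotated LADs held 0 to 57 members (95% range), so this test could not call it. Against all other genes the Nanopore share was 25.5 points higher, which turned its direction, and the Illumina difference was -25.5 points (Fisher's exact test, adjusted p = 0.00014 and 2.8e-07), a test that treats neighbours as independent. Rotation along the gene order, which keeps neighbours together, called it with neither method (permutation, adjusted p = 0.132 and 0.383). Hox genes, which pattern the body axis, had 8 of 39 members in Nanopore LADs and 5 in Illumina LADs. Hoxb1, Hoxb2 and Hoxd1 were among those in both, Hoxa2 in Illumina LADs only and Hoxc12, Hoxc13, Hoxd3 and Hoxd4 in Nanopore LADs only. Hox genes were not called (permutation by rotation, adjusted p = 0.174 and 0.257). Rotated LADs of either method held 0 to 39 of them (95% range), so the test could not call them.

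**Figure D3:**
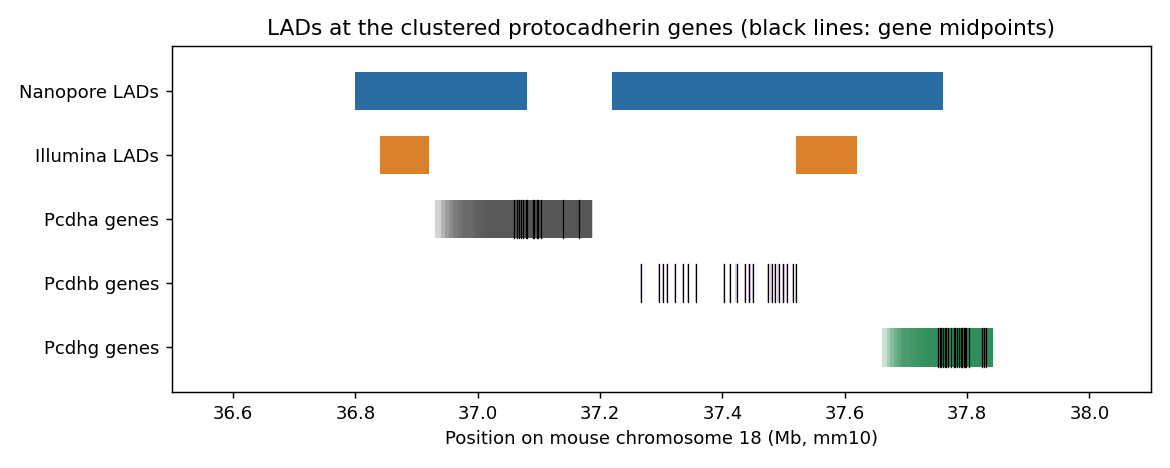
Map of the clustered protocadherin genes on mouse chromosome 18 (position in Mb, mm10, horizontal axis) with Nanopore LADs (blue), Illumina LADs (orange) and genes by subcluster (shaded bars, with black lines at midpoints). The 22 Pcdhb midpoints lie within the Nanopore LAD that starts at 37220001 and left of the Illumina LAD that starts at 37520001.

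Some regions were in the list of a single method. Among the 10 widest in Nanopore LADs only were 1.04 Mb of chromosome 13 (113260001 to 114300000) with Arl15, Cspg4b and Snx18, 1.02 Mb of chromosome X (96240001 to 97260000) with Hsf3, Heph and Vsig4, 0.94 Mb of chromosome X (78000001 to 78940000) with Prrg1, Obp1a and Obp1b, 1.18 Mb of chromosome 9 (84400001 to 85580000) with Tent5a and 0.88 Mb of chromosome 15 (62940001 to 63820000) with Gsdmc. The widest, 1.62 Mb of chromosome 5 (46340001 to 47960000), held no protein-coding gene. The widest in Illumina LADs only was 0.5 Mb of chromosome 8 (12040001 to 12540000) with Sox1, a neural transcription factor gene, then 0.48 Mb of chromosome 7 (43700001 to 44180000) with the kallikrein genes Klk1b21, Klk1b16 and Klk5. Slc25a48, Tgfbi and Lect2 on chromosome 13, Scgb1b29 on chromosome 7, and Sh2d1a and Tex13d on chromosome X lay in others. Of 26 kallikrein genes, 20 lay in Illumina LADs and 0 in Nanopore LADs, the reverse of the protocadherins. Their share was not called in the gene order (permutation by rotation, adjusted p = 0.808 by Nanopore and 0.522 by Illumina). Nanopore-only regions had 6.36 ± 2.19 protein-coding genes per Mb and Illumina-only regions 8.87 ± 5.48 (SD over 20 chromosomes), which did not pass the test (difference -2.51, 2-sided sign-flip permutation test, p = 0.0608). With regions of at least 100 kb the difference was -5.49 and passed (permutation, p = 0.0294). Most Illumina-only regions fall out by that cut, as their median width was 20 kb, and the number left per chromosome is not given here. On autosomes alone the difference was -2.50 and did not pass (permutation, p = 0.0751). Nanopore-only regions were denser than shared LADs by 2.23 genes per Mb, on 18 of 20 chromosomes (permutation, p = 0.00038). Against regions in neither list the difference was -7.60 genes per Mb, with Nanopore-only regions denser on 1 of 20 chromosomes (permutation, p = 1e-05).

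The last comparison asked how CTCF peaks were spread over the genome of HEK293T cells. CTCF is a zinc finger protein found at the bases of many chromatin loops. The list held 10912 peaks on chromosomes 1 to 22 and X, covering 65.2 Mb (hg38) with a median width of 4.03 kb. Chromosome 22 was densest at 13.1 peaks per Mb between its first and last peak, then chromosome 19 at 11.4 and chromosome 17 at 7.06. With peaks under 10 kb apart joined, an alternative chosen after the data were seen, these fell to 8.48, 6.80 and 4.79. Chromosomes 21 (1.12), 4 (1.14) and 18 (1.44) were sparsest. Peaks differed between chromosomes by more than random draws by length gave, with a chi-square of 3502 against a highest of 64.8 in 100000 draws (Monte Carlo exact test, p = 1e-05). The draws take peaks as independent, which clustered peaks are not, so the test overstates the evidence. HEK293T cells carry extra and lost chromosome copies, which the list does not record.

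**Figure D4:**
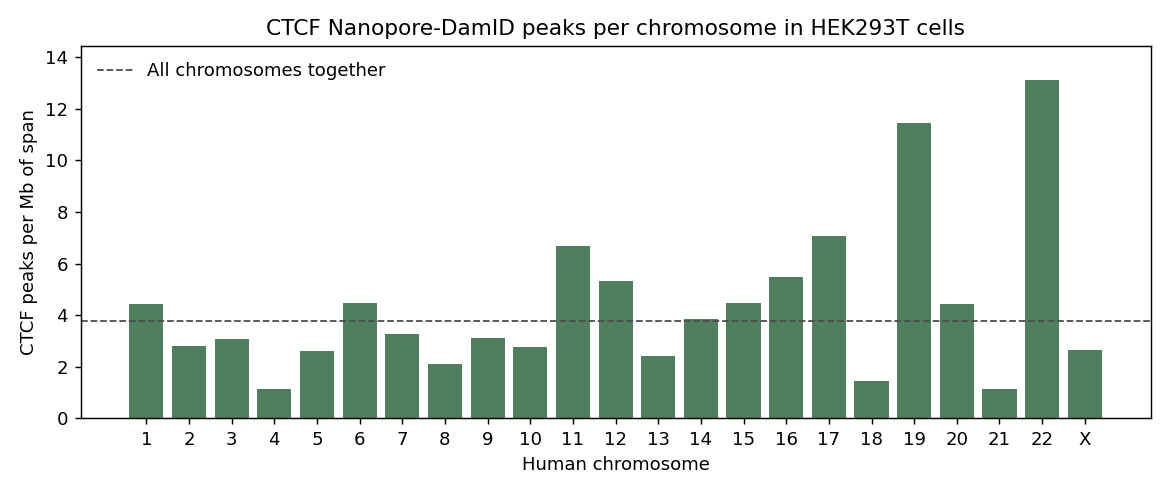
CTCF peaks per Mb between the first and last peak (vertical axis) on each human chromosome (horizontal axis) in the HEK293T list, with a dashed line for all chromosomes together. Each bar is 1 pooled list, without error bars; chromosomes 22 (13.1) and 19 (11.4) stand highest and chromosome 21 (1.12) lowest.

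Peaks lay in clusters. The densest 1 Mb windows were chromosome 11 from 65000001 to 66000000 with 48 peaks and from 62000001 to 63000000 with 45, chromosome 12 from 53000001 to 54000000 with 41, and chromosomes 12 from 121000001 and 17 from 7000001 with 38 each. In 1000 random sets of points no window held more than 30. Of 2901 windows, 902 (31.1%) held no peak, against 6.90% for the random points. Those points could fall anywhere in the span, including the widest gap of 21.7 Mb. Stretches that cannot hold a mapped peak are not known here, so the share of empty windows does not by itself show clustering. Gaps under 10 kb made up 2848 of 10889 gaps (26.2%), against 5.03% on average and 5.76% at most at random (1-sided permutation by random placement, p = 0.001, the smallest that 1000 placements can give). The widest peak ran over 2.30 Mb of chromosome 5 (47306456 to 49610617) and the next over 169.6 kb of chromosome 16 (34411570 to 34581145), and without peaks over 20 kb the share of short gaps was 25.3%. The widest alone held 3.54% of the bases covered, and whether intervals this wide mark CTCF sites was not tested.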

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

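Parts of the genome outside the comparisons carried LADs in both lists. The mitochondrial genome, which is not in the nucleus, was listed as a LAD over 16299 bp by Nanopore and by Illumina. Unplaced scaffolds carried LADs on 29 sequences by Nanopore and 30 by Illumina, 28 of them in both. Chromosome Y had 240 kb in Nanopore LADs and 300 kb in Illumina LADs. No values of the Dam-only or wild-type samples stand beside these, as those samples were not analysed here.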

How the results depend on the processing

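No paired analysis was possible because the lists hold consensus intervals without per-sample values, and for the same reason no replicate could be left out. Of 50 alternatives to main results with a test, 49 kept their direction and side of the threshold. With regions of at least 100 kb, the gene density difference between regions of a single method passed the test at -5.49 per Mb. Of 10 alternative counts of called gene lists, 9 were within 1.5 times the main count, which says nothing of their directions. By rotation along the sequence 3 lists were called above and 8 below with each method. Fisher's exact test called 17 lists by Nanopore, 11 above and 6 below, and 16 by Illumina, 10 above and 6 below. Rotation along the gene order called 12 by Nanopore, 7 above and 5 below, and 13 by Illumina, 8 above and 5 below. Direction turned in 25 list alternatives, given as points above the comparison share. Against other genes in Fisher's test, these were by Nanopore protocadherins 25.5, UDP-glucuronosyltransferases 30.2, glutamate receptors 26.7, Zfp 4.42, liver 17.8, muscle 18.2 and imprinted genes 0.254, and by Illumina Zfp 3.88, liver 21.3, muscle 15.8, blood and immune 1.26 and imprinted genes 7.93. Along the gene order, chosen after seeing the data, they were by Nanopore protocadherins 26.0, UDP-glucuronosyltransferases 32.3, glutamate receptors 25.5, Zfp 3.56, liver 18.3 and muscle genes 20.5, and by Illumina Zfp 2.70, liver 22.3, muscle 17.2 and imprinted genes 3.61. With any overlap, protocadherins by Nanopore reached 28.8 and glutamate receptors by Illumina -5.72, and with whole genes UDP-glucuronosyltransferases by Nanopore 1.68; for these the cause was not tested. Only protocadherins, UDP-glucuronosyltransferases and glutamate receptors passed after the turn, all by Nanopore in Fisher's test and glutamate receptors also along the gene order. Against other genes the comparison share is lower by construction, since protein-coding genes are sparse in LADs. Of 250 list alternatives, 194 kept direction and side, 22 gained a call and 9 lost it without a turn. Merging LADs under 50 kb apart changed nothing, as no gap was under 60 kb. Regions of a single method had a minimum width of 10 kb. Dropping it left their density difference at -2.51, as all borders lay on the 20 kb grid. Those alternatives could not differ, so their places among the 49 are no evidence of stability. Merging under 200 kb, chromosome Y, any overlap, whole genes for gene density, joined CTCF peaks and every alternative for CTCF clustering were also chosen after seeing the data. Not run, for want of sequence or human annotation here: GC content, GATC density and repeats, CTCF motifs and promoters, and human gene lists. Depth is unknown, so nothing can be said of what deeper sequencing would add.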

Other observations

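The tests of gene families, gene biotypes and CTCF gaps, the rotation behind the share of touching pieces, the test of pieces that lie apart, the width limit in the test of narrow LADs and the values by gene length and for microRNA genes were chosen after the data were seen. Among 140 families of at least 15 genes outside the fixed lists, 4 by Nanopore and 6 by Illumina were above their share in the gene order (2-sided permutation by rotation, Benjamini-Hochberg over the families). Pramel genes, expressed in germ cells, had 45 and 42 of 47 members in LADs, Serpina protease inhibitor genes 24 and 24 of 24, Nlrp genes 14 and 14 of 18 and the axonemal dynein Dnah genes 11 and 9 of 15. Prolactin family genes (26 of 26) and Sult sulfotransferase genes (16 of 21) had equal counts with both methods and passed by Illumina alone (permutation, adjusted p = 0.0399 and 0.0383, against 0.065 and 0.0653 by Nanopore). Families below numbered 23 and 28, among them Polr RNA polymerase subunit genes (0 of 27 with each method), Rab genes (6 and 3 of 69) and Eif translation factor genes (3 and 3 of 55). Against the sequence, a test in which genes in general fall below rotation, transfer RNA genes had 55 and 56 of 403 in LADs against 58.3% and 52.9% for rotated LADs (permutation by rotation, adjusted p = 0.0004 for each). Immune receptor V segments had 356 and 342 of 374 in LADs (permutation by rotation, adjusted p = 0.0262 and 0.0516).

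Very long genes had a high share in LADs. Of 227 protein-coding genes of 500 kb or more, 153 (67.4%, 95% Wilson interval 61.1 to 73.2%) were in LADs of both lists, against 17.3% (16.5 to 18.2%) of 7521 genes of 20 to 100 kb. Genes under 5 kb reached 42.2%, and 25.9% without olfactory and vomeronasal receptors. These intervals cover counting error only and take genes as independent, which neighbours are not. Long genes make up the neural adhesion list too, so the list and the length class are not separate evidence. MicroRNA genes differed between the lists, with 25.7% of 1228 in Nanopore LADs and 14.0% in Illumina LADs. Of 146 in Nanopore LADs only, 72 lay within the Sfmbt2 gene on chromosome 2 (10466663 to 10518279) and 40 on chromosome 12 (109682197 to 109747960) up to and into Mirg, while the imprinted genes Meg3 and Dlk1, at lower coordinates, were in neither list. Whether the methods differ at these loci was not tested.

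Nanopore LADs covered more bases, on 20 of 20 chromosomes, which argues against a few chromosomes with another copy number as the whole cause. Of the Nanopore-only bases, 70.6% lay in pieces that touch an Illumina LAD, but what is left of an overlapping LAD touches by construction, and rotated Nanopore LADs gave 71.6% (66.4 to 76.6% over 1000 rotations), so this share does not bear on where borders were set. The other 29.4% (42.3 Mb) lay apart from Illumina LADs, which argues against borders set further out around the same domains as the whole cause. Of borders in 824 LAD pairs matched to each other alone, 726 lay further out by Nanopore, 273 further in and 649 were identical, with a mean shift of 29.6 kb outward and a median of 0 kb. Whether such outward borders account for the touching pieces stays open, as do the callers' thresholds. For this and the patterns below no biological explanation was tested.

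Narrow LADs were shared less often than wide ones. If border jitter on the grid were the cause, narrow LADs that miss the 50% rule would still touch the other list. Of 143 such LADs under 200 kb, 23 were at most 40 kb wide, where a shared bin already meets the rule, so they decide nothing. Of the 120 wider ones, 11 (9.17%) shared a base, which argues against it. Calls near a threshold could also give this, and were not tested.

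CTCF peaks lay closer together than random placement, and single sites split into several intervals could give that. The quartiles of the gaps had been seen when this test was written. After joining peaks under 10 kb apart into 8064 regions, 48.5% of gaps were 10 to 100 kb. Random placements gave at most 26.4%, and 28.2% with each chromosome's widest gap left out. Joining removes every gap under 10 kb, while the random placements keep theirs. The median gap before joining, 53.1 kb, already put the share above both limits. The test could therefore not come out otherwise, and it cannot tell whether splitting is the whole cause. Clustering of genes and open chromatin stays open, as it was not tested.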
